A study of Mus musculus with 12 samples.

How the data were processed

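RNA sequencing libraries of mouse bone marrow-derived macrophages were analysed in 3 groups of 4: macrophages alone, with control melanoma corpses and with STC1-overexpressing corpses. Groups and replicate numbers were taken from the sample titles. The deposited values are raw read counts per gene, 1 file per library, with 55604 genes each; per the submitters' processing notes, HISAT2, HTSeq and DESeq2 were used, without versions, and the builds mm10 and GRCm38 were named. The annotation release is not given in the sources used here. Per the labels, mRNA libraries were made with Illumina TruSeq chemistry and sequenced as paired reads on a NovaSeq. Lines of each deposited count file that name no gene (no feature, ambiguous, low quality, not aligned, not unique) were left out of library sizes and tests. They held 10.55% to 14.69%, 5.53% to 6.62%, 5.17% to 5.85%, 10.81% to 17.77% and 5.74% to 7.03% of all reads. Because strand use in counting is not stated, overlapping and antisense genes cannot be told apart, and near-identical copies share reads.

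Gene symbols were matched by identifier without version, which gave a symbol to 54723 genes and none to 881. Coordinates are those of GRCm38. Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr with a minimum count of 10 and a minimum total of 15, TMM factors, and quasi-likelihood fits with robust dispersion on all 12 libraries with a mean per group, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A total of 16406 genes were tested, in libraries of 28488441 to 39981074 counts. CPM are TMM-scaled, except those of Stc1 and its ratios, which are per total of assigned counts. The 27 gene lists, with 538 genes, were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Most called genes lie below 1.5-fold, so a call here says little about size. Exact permutation tests were two-sided over 70 arrangements, or 35 with 1 library left out.

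The naming rule took Stc1, up to 3 called members of each list with the largest log2 fold change and at least 2 CPM (or 2 abundant members, as values only, where none was called), the 8 highest and 8 lowest called genes above 1 CPM in macrophages alone, the 5 highest and 5 lowest below it, and the 3 smallest p-values per direction. Ranked genes had to be protein coding, with a mean of at least 2 CPM and with ranges that did not overlap. Not every admitted gene is named, and some are not reported here. Symbols of unnamed gene models were left out. Pmel and the chemokine receptor genes Ccr1, Ccr2 and Cxcr2 fall outside the rule and were chosen after their values were seen. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined.

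The steps were tested on simulated data with 200 of 16406 genes changed. For control corpses against macrophages alone, edgeR called 35.8% of genes changed 1.2-fold, 70.1% at 1.5-fold and 80.3% at 2-fold, with 9 false calls. For STC1-overexpressing corpses against macrophages alone the shares were 32.8%, 71.6% and 84.8%, with 9 false calls, and between the corpse groups 41.8%, 59.7% and 87.9%, with 12. The raised list was called in each comparison, and 0 of 26 unchanged lists. Simulated genes were drawn independently, so this does not test false calls of lists whose members move together. Real lists had estimated correlations up to 0.681, for type I interferon.

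Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 2.73 to 17.1, so none was treated as a repeat of another. Libraries 1 and 2 (3.12 and 4.26) and libraries 3 and 4 (2.88 and 2.81) resembled each other in macrophages alone and in the STC1 group, where pairs across gave 6.00 to 13.5 and 11.2 to 17.1. With control corpses libraries 3 and 4 did (2.73), but libraries 1 and 2 (7.03) lay within the 5.46 to 9.11 of pairs across. No label gives a reason, and the SD and tests with n = 4 treat these libraries as independent. Over 4859 genes, the difference between libraries 1 and 2 and libraries 3 and 4 was compared between groups. It correlated at 0.351 between macrophages alone and control corpses, but at −0.421 between macrophages alone and the STC1 group. Between the corpse groups the correlation was −0.0988. A term for these pairs cannot remove a difference that reverses between groups, so calls between the corpse groups may partly reflect it. Alternatives were other scalings (RLE, upper quartile, macrophage-expressed genes), no low-count filter, DESeq2 1.42.0, only the groups compared, a replicate block, the melanocyte score as a covariate, a test against 1.2-fold, and each library left out in turn. Alternatives chosen after seeing the data were replicates 1 and 2 or 3 and 4 of each group alone, summed or as a term, removal of trends on GC content and length, and leaving out replicates 3 and 4 of the STC1 group. Unaligned reads were not analysed here.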

Results

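RNA was sequenced from mouse bone marrow-derived macrophages, grown from C57BL/6 marrow with the growth factor M-CSF at 20 ng/ml and used on day 7. There were 3 groups of 4 libraries: macrophages alone, macrophages given corpses of control B16-F10 cells, a mouse melanoma line, and macrophages given corpses of B16-F10 cells overexpressing STC1, a secreted glycoprotein. Corpses were added at 5 per macrophage, and unbound corpses were washed off after 20 h. The series' design text states that each condition was sequenced from independent experiments. Counts assigned to genes ranged from 28488441 to 39981074 per library, so that a count of 0 allowed up to 0.104 CPM (read counts scaled to library size) in the shallowest library and 0.0746 CPM in the deepest. These floors, like all counting intervals here, cover counting error only. Of the genes counted, 16406 were tested, and the common biological coefficient of variation was 4.53%. Adjusted p-values of genes are from edgeR's quasi-likelihood test and those of gene lists from camera, both with Benjamini-Hochberg adjustment. Values are CPM as mean ± SD with n = 4 per group, and log2 fold changes carry their standard error.

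The first question was whether the overexpressed gene could be seen. Stc1 (ENSMUSG00000014813.9, chromosome 14, 69029238 to 69041804, GRCm38) had 17 counts over the 4 libraries with STC1-overexpressing corpses, 5 with control corpses and 5 in macrophages alone. The mean levels were 0.13 ± 0.07, 0.033 ± 0.039 and 0.039 ± 0.046 CPM, which for Stc1 are per assigned count without TMM factors. The ratio of the corpse groups was 3.68 (counting interval 1.3 to 12.7), which an exact two-sided permutation test did not separate (p = 0.0571, n = 4). Against macrophages alone the ratio was 3.25 (1.15 to 11.3; exact permutation p = 0.0857), and for control corpses it was 0.883 (0.203 to 3.84), also not separated by the exact permutation test. Without replicate 1 of the STC1 group the first 2 ratios were 4.33 and 3.82, each with an exact permutation p of 0.0286. Without replicate 1 of the control corpse group the first and last ratios were 6.6 and 0.492, and without replicate 4 of macrophages alone the second and last were 5.89 and 1.6. Stc1 was too low for the main test. Whether the construct carries mouse Stc1 sequence is not given in the sources used here, so these counts check the labels only in part.

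Transcripts of melanocyte genes were higher with corpses than in macrophages alone, and were lower with STC1-overexpressing than with control corpses. The summed level of the 17 melanocyte markers below 1 CPM in macrophages alone was 1.91 ± 0.238 CPM there, 14.7 ± 1.47 CPM with control corpses and 6.06 ± 0.677 CPM with STC1-overexpressing corpses. Tyrp1, an enzyme of melanin synthesis (chromosome 4, 80834123 to 80851719), stood at 0.0313 ± 0.0233, 4.10 ± 0.642 and 1.05 ± 0.2 CPM. Dct, another enzyme of that pathway, was at 3.07 ± 0.338 CPM with control corpses and lower with STC1-overexpressing corpses (log2 fold change −1.89 ± 0.20, adjusted p = 3.65e-07 by edgeR). The mean log2 CPM of the 7 detected members differed by 1.40 between control corpses and macrophages alone, by 0.83 between STC1-overexpressing corpses and macrophages alone, and by −0.57 between the corpse groups. Each difference had an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 libraries allow (0.0286 after adjustment over the 3 tests).

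**Figure D1:**
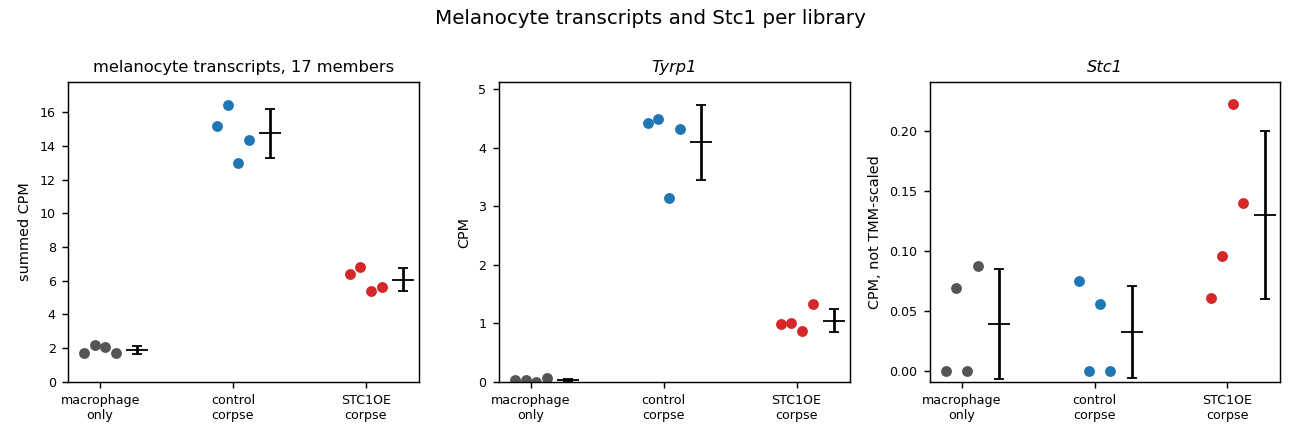
Summed CPM of 17 melanocyte markers, and CPM of Tyrp1 and of Stc1, in each library of the 3 groups; points are libraries, and the bar beside them is the mean ± SD (n = 4). Melanocyte markers averaged 14.7 CPM with control corpses and 6.06 CPM with STC1-overexpressing corpses, while Stc1, whose CPM are not TMM-scaled, stayed at or below 0.223 CPM in every library.

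What changed with control corpses was asked by comparing these libraries with macrophages alone. Cholesterol synthesis fell, while genes of protein folding in the endoplasmic reticulum rose. Genes of lipid handling and of lysosomes rose as well, but camera gave adjusted p = 0.0554 and adjusted p = 0.056 with an estimated correlation. Idi1, an enzyme of isoprenoid synthesis, fell from 12.7 ± 0.864 to 3.01 ± 0.428 CPM (log2 fold change −2.07 ± 0.10, adjusted p = 1.13e-16 by edgeR). Plin2, which coats lipid droplets, rose from 1466 ± 20.5 to 3508 ± 77 CPM (1.26 ± 0.02, adjusted p = 7.63e-27 by edgeR). At an adjusted p below 0.05, 3226 genes were higher and 3356 lower. Most changes were small: the median called gene moved 1.21-fold, and 122 of the higher and 210 of the lower genes passed 2-fold.

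Of the 24 cholesterol biosynthesis genes tested, 21 fell and 1 rose, the same numbers as when adjusted over the list alone (median −1.11, camera adjusted p = 7.87e-20). Cyp51, which demethylates lanosterol, fell from 56.1 ± 2.82 to 16.8 ± 0.55 CPM (−1.74 ± 0.04). Among 25 LXR and PPAR targets of lipid handling, 17 rose and 4 fell, also when adjusted over the list alone (median 0.43, camera adjusted p = 3.54e-08). That call was lost at adjusted p = 0.0554 with an estimated correlation. Angptl4, an inhibitor of lipoprotein lipase, rose by 1.23 ± 0.06, and Fabp5, a fatty acid-binding protein, by 1.10 ± 0.03 on the log2 scale. In the list of the unfolded protein response and its chaperones 17 of 21 rose and 2 fell, as when adjusted over the list alone (median 0.57, camera adjusted p = 5.72e-15). Calr, the chaperone calreticulin (chromosome 8, 84841850 to 84846934), rose from 873.4 ± 21.6 to 1790 ± 22.4 CPM. Of 35 lysosomal genes 31 rose and 2 fell, as when adjusted over the list alone (median 0.33, camera adjusted p = 7.61e-18). The camera result was adjusted p = 0.056 with an estimated correlation. Gaa, which degrades glycogen, rose by 0.79 ± 0.04, and Acp5, an acid phosphatase, by 1.02 ± 0.07 on the log2 scale.

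Genes of antigen presentation to CD4 T cells fell. In the MHC class II list 9 of 11 fell and 1 rose, as when adjusted over the list alone (median −0.79, camera adjusted p = 1.52e-07). Ciita, the transactivator of these genes, fell from 7.07 ± 0.832 to 1.74 ± 0.307 CPM, and Cd74, the invariant chain, from 144.0 ± 3.54 to 60.3 ± 1.05 CPM. Ighm, a marker of B cells, which also carry MHC class II, fell as well, from 12.5 ± 0.824 to 2.55 ± 0.418 CPM with control and 2.50 ± 0.254 CPM with STC1-overexpressing corpses. The B cell markers Cd79a and Cd79b were not called with control corpses. With STC1-overexpressing corpses 2 of the 3 B cell markers tested were lower than in macrophages alone. A loss of other cells was not tested. Of 29 type I interferon response genes 26 rose and 0 fell, also when adjusted over the list alone (median 0.65, camera adjusted p = 2.02e-14), but adjusted p = 0.226 with an estimated correlation. Rsad2, an antiviral enzyme, rose from 35.1 ± 2.88 to 85.4 ± 16.1 CPM. Of 20 inflammatory cytokine and chemokine genes 11 rose and 5 fell, or 11 and 6 when adjusted over the list alone (median 0.35, camera adjusted p = 0.0427). That list gave adjusted p = 0.442 with an estimated correlation, and its call was also lost without replicate 3 of the control corpse group (camera adjusted p = 0.065) or replicate 1 of the STC1 group (0.0593). Ccl2, a chemokine for monocytes, rose from 28.2 ± 2.38 to 84.1 ± 13.2 CPM, and Nfkbiz fell by 0.78 on the log2 scale.

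All 7 neutrophil markers tested fell, also when adjusted over the list alone (median −1.53, camera adjusted p = 2.18e-06). S100a9 fell from 4.17 ± 0.454 to 0.513 ± 0.166 CPM and Mmp8 from 166.7 ± 3.94 to 90.3 ± 1.73 CPM. Their levels and the size of their falls differed widely, and which cells these transcripts came from was not tested. Of 12 melanocyte markers 11 rose and 0 fell, as when adjusted over the list alone (median 2.92, camera adjusted p = 3.54e-08). Further lists were called by camera with the preset correlation only. MHC class I genes had 14 of 23 higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 0.00254, and adjusted p = 0.226 with an estimated correlation). In all comparisons that list shares Calr, Canx and Pdia3 with the list of the unfolded protein response, so the results of these lists are not separate. Cell cycle genes had 12 of 30 higher and 4 lower (adjusted over the list alone 13 and 5; adjusted p = 0.00742, and adjusted p = 0.494 with an estimated correlation). Oxidative phosphorylation genes had 10 of 29 higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 0.014, and adjusted p = 0.265 with an estimated correlation). NRF2 and iron genes had 10 of 20 higher and 5 lower, also when adjusted over the list alone (camera adjusted p = 0.0265, and adjusted p = 0.246 with an estimated correlation). Hmox1, the heme-degrading enzyme, rose from 545.9 ± 10.6 to 1230 ± 38.1 CPM, and Slc7a11, a cystine transporter, fell from 32.0 ± 1.85 to 18.4 ± 1.21 CPM. ATF4 targets had 5 of 23 higher and 15 lower, also when adjusted over the list alone (camera adjusted p = 0.014, and adjusted p = 0.236 with an estimated correlation). Alternative activation genes had 2 of 16 higher and 7 lower, or 2 and 8 when adjusted over the list alone (camera adjusted p = 0.0265, and adjusted p = 0.182 with an estimated correlation).

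The efferocytosis list, which holds receptors and bridging molecules for dying cells, went both ways: 14 of 30 members rose and 12 fell, also when adjusted over the list alone (camera adjusted p = 0.349). Marco, a scavenger receptor, rose from 0.602 ± 0.0135 to 3.64 ± 0.327 CPM, while Cx3cr1, the fractalkine receptor, fell from 8.05 ± 0.382 to 3.14 ± 0.191 CPM. Camera also called none of the following lists, whose higher and lower members adjusted over the list alone are in brackets. T cell costimulation had 3 and 6 of 16 [3 and 6] and interferon gamma 7 and 2 of 15 [7 and 2]. Glycolysis and hypoxia had 9 and 3 of 24 [9 and 3], mitochondrially encoded mRNAs 4 and 0 of 12 [4 and 0], and core macrophage identity 6 and 11 of 19 [6 and 12]. Dendritic cell markers had 1 and 2 of 6 [1 and 2], T and NK cell markers 0 and 0 of 2 [0 and 0], and B cell markers 0 and 1 of 3 [0 and 1]. Fibroblast markers had 0 and 3 of 8 [0 and 2], mast cell and basophil markers 0 and 1 of 2 [0 and 1], and osteoclast markers 3 and 5 of 8 [3 and 5]. In all, 15 of 27 lists were called, 5 of them with an estimated correlation. Of the 80 genes called among those admitted by the naming rule, 77 kept their call with any 1 library left out. Cd24a, Gata2 and Pld4 lost it in at least 1 case.

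**Figure D2:**
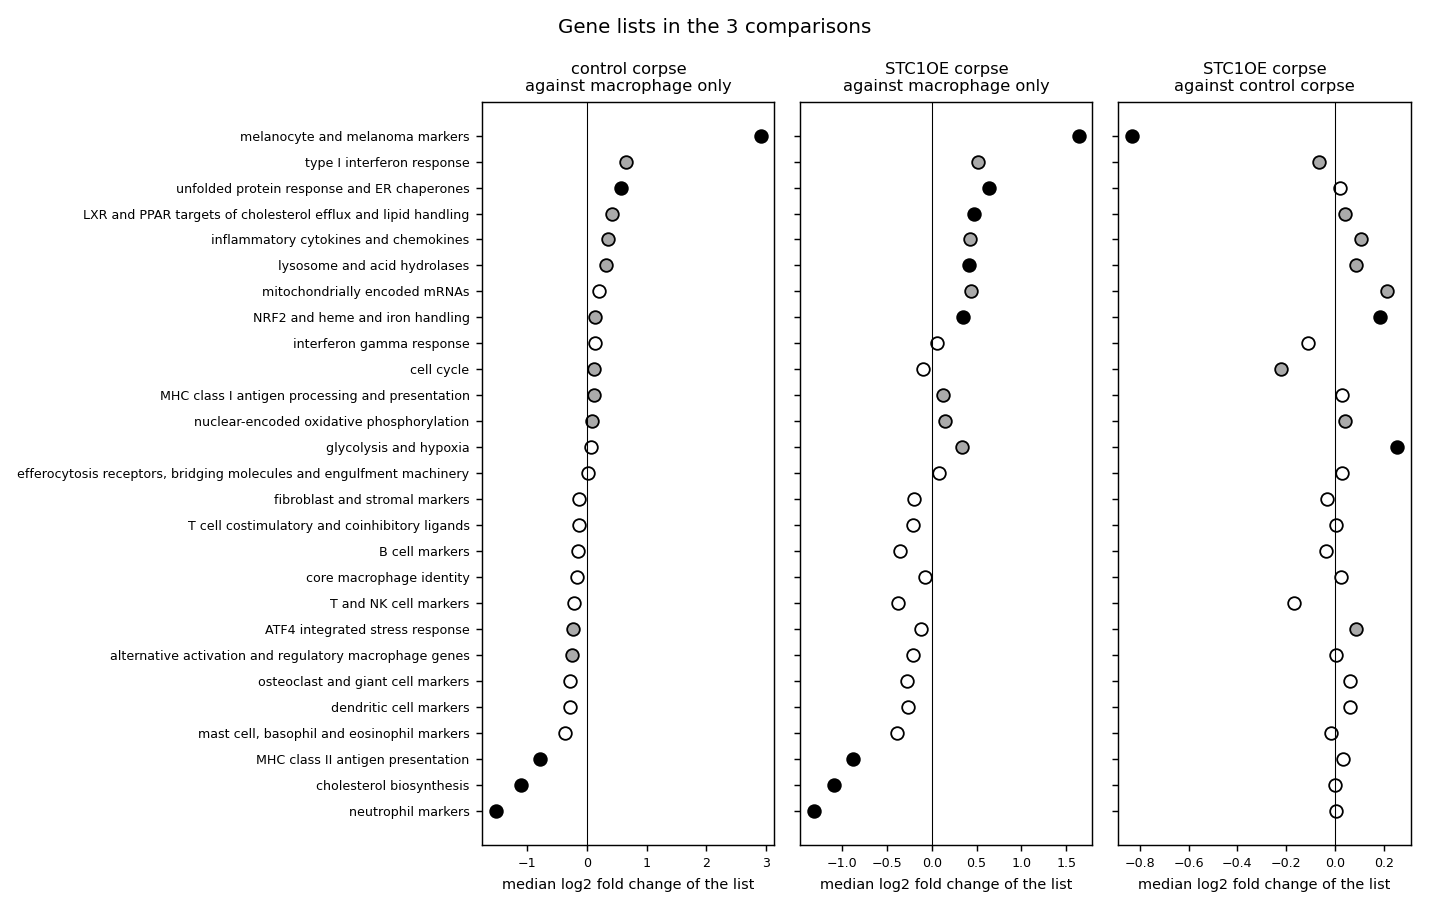
Median log2 fold change of each of 27 gene lists in the 3 comparisons (each panel has its own axis); black points were called by camera with both correlation settings, grey points with the preset correlation only, and white points were not called. With control corpses the medians ran from −1.53 for neutrophil markers to 2.92 for melanocyte markers.

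With STC1-overexpressing corpses, compared with macrophages alone, genes of cholesterol synthesis fell and those of lysosomes and protein folding rose. Cholesterol biosynthesis fell in 21 of 24 genes and rose in 1, also when adjusted over the list alone (median −1.09, camera adjusted p = 2.6e-17). Hmox1 (chromosome 8, 75093621 to 75100589) rose from 545.9 ± 10.6 to 1528 ± 43.8 CPM (1.48 ± 0.03, adjusted p = 3.34e-27 by edgeR), and Egln3, a prolyl hydroxylase induced by hypoxia, from 2.39 ± 0.474 to 5.80 ± 0.318 CPM (1.27 ± 0.12). At an adjusted p below 0.05, 3510 genes were higher and 3676 lower, of which 124 and 297 passed 2-fold.

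Of 24 glycolysis and hypoxia genes 19 rose and 3 fell, also when adjusted over the list alone (median 0.34, camera adjusted p = 8.22e-09), with adjusted p = 0.12 with an estimated correlation. Hk2, which phosphorylates glucose, rose by 0.66 on the log2 scale from 99.0 ± 3.36 CPM, and Gapdh from 110.5 ± 1.7 to 173.2 ± 8.32 CPM. NRF2 and iron genes rose in 13 of 20 and fell in 1, or 14 and 2 when adjusted over the list alone (median 0.35, camera adjusted p = 1.59e-06). Gsr, which reduces glutathione, rose from 78.1 ± 2.42 to 137.4 ± 5.62 CPM. Lysosomal genes rose in 33 of 35 and fell in 2, also when adjusted over the list alone (median 0.41, camera adjusted p = 5.92e-21). Chaperones of the unfolded protein response rose in 17 of 21 and fell in 2, or 18 and 2 when adjusted over the list alone (median 0.64, camera adjusted p = 1.19e-14). LXR and PPAR targets rose in 18 of 25 and fell in 3, or 18 and 4 when adjusted over the list alone (median 0.47, camera adjusted p = 1.93e-09). MHC class II genes fell in 9 of 11 and rose in 1, also when adjusted over the list alone (median −0.88, camera adjusted p = 1.51e-06). All 7 neutrophil markers fell, also when adjusted over the list alone (camera adjusted p = 1e-05), and 11 of 12 melanocyte markers rose, also when adjusted over the list alone (median 1.65, camera adjusted p = 2.56e-05).

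Type I interferon genes rose in 24 of 29, or 26 when adjusted over the list alone, and none fell by edgeR (camera adjusted p = 4.93e-11, and adjusted p = 0.235 with an estimated correlation). Mitochondrially encoded mRNAs rose in 6 of 12, also when adjusted over the list alone (camera adjusted p = 0.00193, and adjusted p = 0.371 with an estimated correlation). mt-Nd1 rose by 0.64 on the log2 scale. The share of counts on all mitochondrial genes was 3.82% ± 0.545, against 3.73% ± 0.545 in macrophages alone (exact permutation p = 0.714). It was highest in libraries 1 and 2 of macrophages alone (4.36% and 4.00%) and in libraries 3 and 4 of the STC1 group (4.29% each). Oxidative phosphorylation genes rose in 15 of 29 and fell in 2, or 16 and 3 when adjusted over the list alone (camera adjusted p = 0.000655, and adjusted p = 0.189 with an estimated correlation). MHC class I genes rose in 13 of 23 and fell in 2, or 15 and 3 when adjusted over the list alone (camera adjusted p = 0.000655, and adjusted p = 0.189 with an estimated correlation). Inflammatory genes rose in 11 of 20 and fell in 5, also when adjusted over the list alone (camera adjusted p = 0.00412, and adjusted p = 0.302 with an estimated correlation). Lists without a camera call follow as higher and lower members, with those adjusted over the list alone in brackets. They were efferocytosis with 15 and 10 of 30 [15 and 10], T cell costimulation with 3 and 7 of 16 [3 and 7], and interferon gamma with 5 and 3 of 15 [6 and 5]. Alternative activation had 2 and 5 of 16 [2 and 5], ATF4 targets 4 and 10 of 23 [5 and 10], cell cycle 7 and 10 of 30 [7 and 11], and core macrophage identity 7 and 9 of 19 [7 and 10]. Dendritic cell markers had 1 and 3 of 6 [1 and 3], T and NK cell markers 1 and 1 of 2 [1 and 1], and B cell markers 0 and 2 of 3 [0 and 2]. Fibroblast markers had 0 and 2 of 8 [0 and 2], mast cell and basophil markers 0 and 1 of 2 [0 and 1], and osteoclast markers 3 and 5 of 8 [3 and 5]. For T and NK cell markers the median was −0.38 while camera's direction was up (adjusted p = 0.976). In all, 14 lists were called, 8 of them with an estimated correlation. Of the 83 genes called under the naming rule, Cd4 and Erbb3 lost their call with some library left out.

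The calls of the corpse groups overlapped: 2677 genes were higher in both and 2792 lower in both, and 8 were called in opposite directions. Independent lists of these lengths would share 690 and 752 genes. Simulated groups without any effect, set against the same macrophage libraries, shared at most 0 and 1 over 20 simulations. Groups without an effect give few calls by construction, so these counts do not measure what the shared libraries add to the overlap. With the macrophage libraries split so that no library served both comparisons, 2057 to 2115 genes were higher and 2094 to 2150 lower in both. Across genes, which are not independent replicates, the covariance of the log2 fold changes was 0.129 against 0.0164 in simulated unchanged groups, a difference of 0.112, and the correlation was 0.838 against 0.509.

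Compared directly with control corpses, libraries with STC1-overexpressing corpses held more mRNA of glycolysis, hypoxia and NRF2 genes and less of melanocyte genes. The differences were small. RNA of macrophages and of corpses was not separated, so a called gene may reflect either. Egln3 (chromosome 12, 54178981 to 54203860) was higher at 5.80 ± 0.318 against 2.66 ± 0.198 CPM (1.12 ± 0.11, adjusted p = 1.71e-07 by edgeR), and Eno1, a glycolytic enzyme, at 1314 ± 33.4 against 1057 ± 30.6 CPM (0.31 ± 0.03, adjusted p = 4.22e-09 by edgeR). At an adjusted p below 0.05, 546 genes were higher and 347 lower. The median called gene moved 1.12-fold, and 4 of the higher and 15 of the lower genes passed 2-fold.

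Of 24 glycolysis and hypoxia genes 21 were higher and 0 lower, or 22 and 0 when adjusted over the list alone (median 0.26, camera adjusted p = 1.79e-38). Slc16a3, a lactate exporter, was at 107.3 ± 4.69 against 76.6 ± 6.56 CPM, and Bnip3, a mitophagy receptor, at 7.86 ± 0.625 against 5.66 ± 0.602 CPM. Of 20 NRF2 and iron genes 14 were higher and 0 lower, or 16 and 0 when adjusted over the list alone (median 0.19, camera adjusted p = 6.81e-21). Hmox1 was at 1528 ± 43.8 against 1230 ± 38.1 CPM, and Gclm, a subunit of the enzyme that starts glutathione synthesis, at 178.6 ± 12 against 141.2 ± 3.09 CPM. Of 12 melanocyte markers 7 were lower and 0 higher by edgeR, or 8 and 0 when adjusted over the list alone (median −0.83, camera adjusted p = 1.68e-06). DESeq2 called only 2 of the 12 lower and 0 higher. These 3 lists kept their call with an estimated correlation.

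Cell cycle genes were lower in 16 of 30 and higher in 0, or 22 and 0 when adjusted over the list alone (median −0.22, camera adjusted p = 3.88e-17, and adjusted p = 0.123 with an estimated correlation). Tk1, a thymidine kinase, was at 20.8 ± 1.11 against 25.4 ± 1.47 CPM, Ccnb1 at 7.36 ± 0.492 against 9.06 ± 0.404 CPM, and Tyms at 8.13 ± 0.377 against 9.97 ± 1.3 CPM. The call of Tyms was lost without control replicate 1 or STC1 replicate 4 (edgeR adjusted p = 0.122 and 0.0736). Lysosomal genes were higher in 17 of 35 and lower in 0, or 22 and 0 when adjusted over the list alone (median 0.09, camera adjusted p = 6.03e-14, and adjusted p = 0.123 with an estimated correlation). Cd68, a lysosomal glycoprotein of macrophages, was at 1749 ± 132 against 1505 ± 33.5 CPM. ATF4 targets were higher in 7 of 23 and lower in 1, or 8 and 1 when adjusted over the list alone (camera adjusted p = 0.000116, and adjusted p = 0.123 with an estimated correlation). LXR and PPAR targets were higher in 3 of 25 and lower in 0, or 8 and 1 when adjusted over the list alone (camera adjusted p = 0.00158, and adjusted p = 0.311 with an estimated correlation). Scd2, a fatty acid desaturase, Npc1, a cholesterol transporter, and Soat1, which esterifies cholesterol, were the members higher, and Soat1 lost its call without control replicate 1 (edgeR adjusted p = 0.0574).

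Inflammatory genes were higher in 2 of 20 and lower in 0, or 3 and 0 when adjusted over the list alone (camera adjusted p = 0.00775, and adjusted p = 0.387 with an estimated correlation). Mitochondrially encoded mRNAs had 0 of 12 called by edgeR, also when adjusted over the list alone (median 0.21, camera adjusted p = 0.000397, and adjusted p = 0.387 with an estimated correlation). Their median was −0.05 in libraries 1 and 2 of each group alone and 0.47 in libraries 3 and 4, so its direction rests on the latter. Oxidative phosphorylation genes had 0 of 29 called by edgeR, also when adjusted over the list alone (camera adjusted p = 0.0134, and adjusted p = 0.385 with an estimated correlation). Their median was 0.04 with camera's direction up, and their mean was −0.06. Type I interferon genes had 0 of 29 called by edgeR, also when adjusted over the list alone (median −0.07, camera adjusted p = 0.023, and adjusted p = 0.724 with an estimated correlation). At an unadjusted edgeR p below 0.05 these 3 lists had 3, 4 and 3 members, and DESeq2 called 1, 2 and 0 of them higher and 0 lower. Lists without a camera call follow as higher and lower members, with those adjusted over the list alone in brackets. MHC class I had 2 and 0 of 23 [2 and 0], MHC class II 1 and 0 of 11 [1 and 0], and efferocytosis 2 and 0 of 30 [5 and 4]. T cell costimulation had 1 and 1 of 16 [4 and 2], interferon gamma 0 and 1 of 15 [0 and 1], and alternative activation 3 and 0 of 16 [3 and 0]. Cholesterol biosynthesis had 0 and 1 of 24 [0 and 1], the unfolded protein response 1 and 0 of 21 [1 and 0], and core macrophage identity 3 and 2 of 19 [3 and 2]. Neutrophil markers had 0 and 1 of 7 [0 and 1], osteoclast markers 0 and 1 of 8 [0 and 1], and dendritic cell, T and NK cell, B cell, fibroblast and mast cell markers 0 and 0 [0 and 0] by edgeR, with 0 members at an unadjusted p below 0.05 and 0 by DESeq2. The median or mean and camera's direction differed in sign for alternative activation, neutrophil, T and NK cell and fibroblast markers, none of which was called.

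Outside the lists, Acod1, the enzyme making itaconate, was at 6.07 ± 0.778 against 3.83 ± 0.382 CPM, Ak4 at 12.5 ± 1.25 against 7.97 ± 1.24 CPM, and Cdkn1c, a cell cycle inhibitor, at 11.7 ± 0.555 against 8.04 ± 0.45 CPM. Neil3, a DNA repair glycosylase, was at 2.52 ± 0.219 against 4.21 ± 0.372 CPM, and the histone gene Hist1h3c at 28.2 ± 1.61 against 36.6 ± 2.78 CPM.

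These counts moved with single libraries and with the setting. Without replicate 3 of the STC1 group 281 genes were higher and 193 lower, and without its replicate 4 486 were called, 340 of them higher. Without replicate 3 of the control group 326 were higher and 203 lower, and without its replicate 1, 185 were lower. DESeq2 gave 753 higher and 268 lower, and removing trends on GC content and gene length gave 334 and 339. Replicates 1 and 2 of each group alone gave 27 and 6, and with the melanocyte score as a covariate edgeR called 0 genes, with 633 at an unadjusted p below 0.05. Of the 54 genes called among those the naming rule admits, 34 kept their call with any 1 library left out and 20 did not, among them Tyms, Soat1, Cd300a, Tnfaip2, Il18 and Vegfa. Each of the 54 lost its call in at least 1 other setting, among them the test against a 1.2-fold change and the covariate. The covariate nearly follows the groups and left 0 calls, so this loss was fixed in advance and does not measure how firm a call is. The inflammatory list lost its call without control replicate 2 (camera adjusted p = 0.197). Oxidative phosphorylation lost it without control replicate 2 or 3 or STC1 replicate 1 (camera adjusted p = 0.0526, 0.106 and 0.0814), and type I interferon without control replicate 3 or STC1 replicate 2 or 4 (0.937, 0.271 and 0.502). Beside these differences, the unaligned share of reads was 16.08% ± 1.82 with STC1-overexpressing and 11.27% ± 0.322 with control corpses (exact permutation p = 0.0286, adjusted p = 0.172 over 24 exact tests, n = 4).

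**Figure D3:**
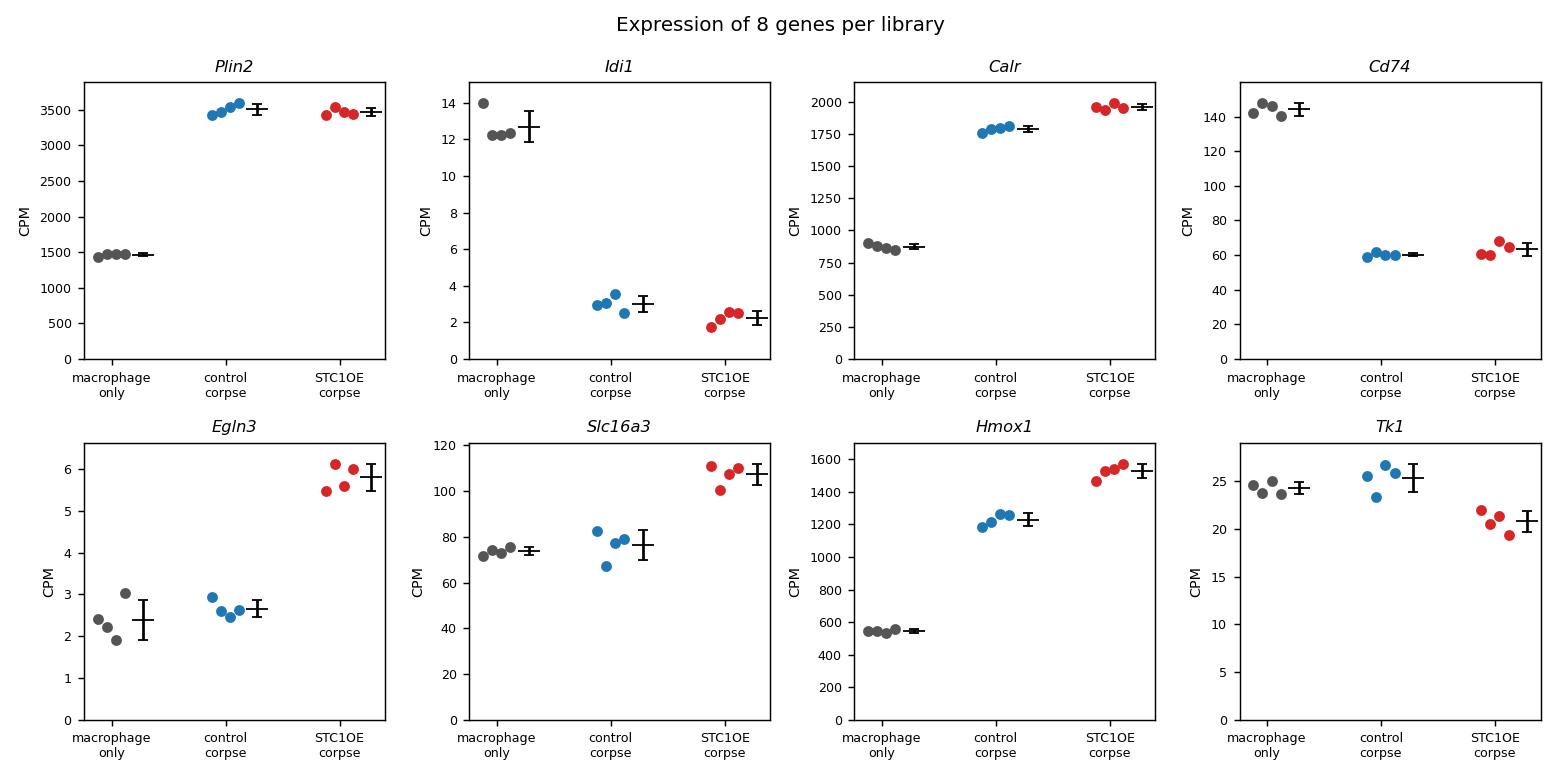
CPM of 8 genes in each library of the 3 groups; points are libraries, and the bar beside them is the mean ± SD (n = 4). Plin2 and Calr were higher and Idi1 and Cd74 lower in both corpse groups, while Egln3 and Slc16a3 were higher with STC1-overexpressing than with control corpses.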

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

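The tests of equal loss (which replaced a comparison of the 3 most abundant members and a simulation with the common dispersion of all genes, p = 1e-04 by chi-square), of a weaker response and of unaligned reads were chosen after the results were seen, and the GC and length correction and the omission of STC1 replicates 3 and 4 after seeing the data.

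Melanocyte transcripts were lower with STC1-overexpressing than with control corpses. With the scale set on macrophage-expressed genes the ratio of their summed CPM was still 0.409, which argues against library scaling as the cause. The planned comparison with 5 other transcripts raised by control corpses decided nothing. Their median remaining share was 110% (3.58 to 140), against 28.7% (13.3 to 59.2) for 5 melanocyte members, with transcripts resampled. One common remaining share for the 9 members raised with control corpses gave a chi-square misfit seldom reached in 10000 simulated data sets (p = 6e-04 with trended dispersions). Tyrp1 was at 25.0% (20.5 to 31.5) and Pmel at 52.9% (42.0 to 68.2), with libraries resampled within groups. This argues against an equal loss of corpse RNA as the whole cause only if macrophages kept their own level of each member. The simulation, a test chosen afterwards, assumed that, and Pmel was at 0.24 CPM in macrophages alone. Fewer corpses taken up together with other pigment gene levels in the overexpressing line, or another rate of decay, may contribute and were not tested.

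Glycolysis and hypoxia genes were higher with STC1-overexpressing corpses, with a list median of 0.26 on the log2 scale. Removing trends on GC content and length left 0.22 (0.218), and leaving out replicates 3 and 4 of the STC1 group left 0.222, so neither accounts for most of it. A weaker response to corpses would need the list to fall with control corpses, where its median was 0.065 (bootstrap interval over members −0.013 to 0.119). Resampling members treats genes that move together as independent and leaves out differences between libraries. A response to STC1 or to other properties of the overexpressing line may underlie it as a hypothesis, since the groups differ in both.

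Unaligned reads made up 16.08% of reads in the STC1 group, above the 10.81% to 14.01% of the other 8 libraries. A library difference that also shows in mitochondrial reads is argued against as the whole cause, since 4 of 4 STC1 libraries lay within the mitochondrial range of the others and above their unaligned shares. It may account for a part, because STC1 libraries 3 and 4, with 4.29% mitochondrial reads each, had 17.77% and 17.53% unaligned, and libraries 1 and 2, with 3.41% and 3.29%, had 14.62% and 14.40%. Read quality could not be decided, since low-quality alignments leave out reads that did not align: their share differed from that with control corpses by −0.192 percentage points of all reads but by 0.136 of aligned reads. Foreign RNA carried in by corpses could not be decided either: the summed melanocyte CPM differed by −8.69 where unaligned reads were more frequent, but such RNA need not follow melanoma transcripts.

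Chance was examined with 35 splits of the 8 libraries. The real split called 6582, 7186 and 893 genes in the 3 comparisons, and the highest other split 1, 3 and 218. Thus 1 split of each set reached the real count, the fewest possible. Splits that mix the groups add the group difference to the spread, which lowers their calls, so this test cannot exclude chance. As for lists, 15, 14 and 11 were called, and other splits reached 15, 15 and 11. In all, 3, 9 and 4 of 35 splits called as many, so chance is not excluded for this number either. The other splits that reached it exchanged a single library per group and so kept part of the real difference; the 18 that put 2 libraries of each group on either side called at most 6, 3 and 8 lists.

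Single libraries stood apart from the other 3 of their group for 19 of 297 groups tested, where chance gives about 14.8 (1 in 20). The test, Dixon's ratio, sets the gap against the range of the group, so a flagged gap can be small. Siglec1, for example, was flagged at 104 CPM against 106 CPM in the others. Pld4 was at 33.8 CPM in STC1 replicate 4 against 2.09 to 2.4 in the others, and the reverse was seen in macrophages alone, with Pld4 at 2.77 CPM in replicate 4 against 24.1 to 28.6 in the others, short of the limit of that test. Tyrp1 was at 3.14 CPM, Slc7a11 at 20.1 CPM and Oasl1 at 10.3 CPM in control corpse replicate 3. Tfrc at 315 CPM, Dcstamp at 10.2 CPM and Ak4 at 6.14 CPM stood apart in control corpse replicate 2, and Gsr at 114 CPM and Acod1 at 3.26 CPM in its replicate 1. In macrophages alone, replicate 1 had Idi1 at 14.0 CPM, Cd300lf at 4.45 CPM and Siglec1 at 104 CPM, and replicate 4 had Cyc1 at 60.4 CPM. In STC1 replicate 1, Il18bp was at 38.2 CPM, Cox5a at 19.7 CPM, Gla at 256 CPM, Ak4 at 14.4 CPM and Npc1 at 411 CPM, and replicate 4 had 5.66% low-quality alignments.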

How the results depend on the processing

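Libraries 1 and 2 or 3 and 4 alone or summed, GC content and length, and leaving out replicates 3 and 4 of the STC1 group were tests chosen after seeing the data. Against a 1.2-fold change 736 and 951, 903 and 1216, and 2 and 2 genes were higher and lower in the 3 comparisons, by the construction of that test. Libraries 1 and 2 alone, with fewer samples, gave 1997 and 2093, 2255 and 2395, and 27 and 6; of these last 33, 31 were shared with the 893. Between the corpse groups, libraries 3 and 4 alone gave 1298 and 627, sums of each pair 288 and 212, leaving out STC1 replicates 3 and 4 114 and 53, and removal of GC and length trends 334 higher; the cause was not tested. The melanocyte score as a covariate, which nearly follows the groups, left 0 and 0 genes by edgeR (633 at an unadjusted p below 0.05) and turned the inflammatory list to −0.185, Vegfa to −0.017, Slc7a11 to −0.058 and Plxdc2 to 0.255. An estimated correlation left 5, 8 and 3 lists, and fry, which asks another question, called 23, 22 and 6. Between the corpse groups the melanocyte list reversed to 0.036 over macrophage-expressed genes, which leave out most members; type I interferon reversed to 0.042 and mitochondrial mRNAs to −0.05 in libraries 1 and 2, and type I interferon ranged from −0.127 (without STC1 replicate 1) to 0.019 (without control replicate 3). With 1 library left out, 281 (without STC1 replicate 3) to 727 genes were higher and about 1.5e+02 (without STC1 replicate 4) to 473 lower between the corpse groups. The Stc1 ratio ranged from 2.38 to 5.89 against macrophages alone and from 2.8 to 6.6 against control corpses. With the replicate block 677 and 412 genes were called between the corpse groups. Same-numbered libraries correlated at −0.0434 to 0.0912, and 0 of 12 pairs passed 0.1. In 6 of 12 the own number was best, where chance among 4 libraries gives 1 in 4 on average. Whether that excess goes beyond chance was not tested. Any pairing by number was therefore weak but is not excluded. Stc1, at 17 counts or fewer per group, is limited by depth.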

Other observations

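All tests of gene families here were chosen after the calls were seen. Of 35 families defined by gene symbols that were looked at, 4 are described, and camera p-values are adjusted over all 105 tests; 36 tests passed, 5 of them with an estimated correlation.

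Chemokine receptors fell with corpses. Of 11 genes 7 were lower and 0 higher with control corpses (median −0.62, camera adjusted p = 0.000124), and 7 and 0 with STC1-overexpressing corpses (median −0.81, camera adjusted p = 3.65e-05). Between the corpse groups 4 were lower and 0 higher (median −0.21, camera adjusted p = 0.000582). Each gave adjusted p = 0.0464 with an estimated correlation, and the medians kept their sign under the other scalings. Ccr2, the receptor for Ccl2, was at 23.2 ± 0.923 CPM in macrophages alone, 7.99 ± 0.366 CPM with control and 6.6 ± 0.872 CPM with STC1-overexpressing corpses, and Ccr1 at 139 ± 3.87, 90.4 ± 3.69 and 78.9 ± 2.83 CPM. One of the 11, Cxcr2, is also among the neutrophil markers, of which 7 of 7 fell with control corpses (median −1.53) and with STC1-overexpressing corpses (median −1.32). Whether the fall of the family follows a change in other cells was not tested.

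With control corpses against macrophages alone, 60 of 77 ribosomal protein genes were lower and 1 higher (median −0.22, camera adjusted p = 1.01e-15), but adjusted p = 0.148 with an estimated correlation. Proteasome subunits were higher in 24 of 38 and lower in 0 (median 0.16, camera adjusted p = 1.35e-05), with adjusted p = 0.128 with an estimated correlation. Glutathione transferases were higher in 9 of 14 and lower in 0 (median 0.36, camera adjusted p = 0.000235), with adjusted p = 0.0888 with an estimated correlation. The medians kept their sign under the other scalings. The remaining calls with both settings were C-type lectins with control corpses (9 of 18 lower, 1 higher) and solute carriers with STC1-overexpressing corpses (97 of 228 higher, 44 lower).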
